A study of Mus musculus with 33 samples.

How the data were processed

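RNA of 1-month-old male mouse cerebellum and cortex was extracted from frozen tissue and made into stranded libraries of polyadenylated RNA, per the labels. The authors deposited 1 table for each of 5 comparisons, each with 38393 features. The counts are whole numbers of reads per gene, per the file headers and values, and the submitters' processing notes name STAR 2.4, HTSeq 0.6.1p1 and DESeq2 1.10 with the builds mm10 and GRCm38. Beside the counts, the deposited tables hold a normalised signal, which is the count divided by 1 size factor per library, with its mean, and the authors' DESeq2 results as log2 fold change, its standard error, a Wald score, a p-value and an adjusted p-value. Whether the counting used strand, how it treated reads with several matches and which annotation release it used are not given in the sources used here, so counts of pseudogenes with near-identical copies, of overlapping genes and of antisense genes are uncertain. The authors added a feature for Cdr1as, which carries no coordinates, so its position is not given. In the CyrMut table the record of Myo15 lacked 1 cell, which was put back in place. Both tables of experiment 1B hold the same wild-type libraries, and 1 count of Cdr1 differs between them.

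Libraries were grouped by the genotype, tissue and experiment in the labels, and only libraries of 1 experiment were compared, as the design text describes it. The submitters describe the replicates as biological. Totals ran from 6.89 to 24.94 M counts per library, and 6 of the 33 libraries held more counts than the read number in their label, so the label read numbers were not used. No pair of libraries in a group agreed within sampling noise, and all were kept.

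Raw counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10, TMM scaling, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05), with the libraries of the comparison alone and no covariate. The standard error of a log2 fold change is its size divided by the root of the F statistic. Levels are CPM on TMM-scaled library sizes. A biological coefficient of variation of 9.02% in CyrMut, 8.98% in CyrKO, 9.79% in Mir7DKO of experiment 1B, 6.14% in cerebellum and 5.56% in cortex of experiment 2 sets the precision beside the counting error. Genes whose 2 groups did not overlap made up 5.39%, 4.05%, 2.54%, 6.70% and 6.99% of the genes tested in these comparisons, where chance gives 5.71%, 2.86%, 2.86%, 5.71% and 5.71%. DESeq2 1.42.0 was the other tool.

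A total of 32 gene lists, 13 of pathways and 19 of cell type markers, were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided, adjusted over the 32 lists), and again with an estimated correlation. A gene was counted as having a miR-7 site where its longest annotated 3′ UTR held GTCTTCC, TCTTCCA or GTCTTCCA (GRCm38 genome and annotation), and as lacking one where it held no 6-mer match, both among genes with a mean normalised count of at least 50. Site genes were tested with camera, by an exact two-sided permutation of the libraries, against 10000 random lists matched on expression and 3′ UTR length, and against 60 shuffled seeds. Changes in 2 comparisons were set against each other by a z test of their difference per gene with Benjamini-Hochberg adjustment. Its p comes from a normal distribution, which makes no allowance for the few libraries per group. These p-values may therefore be too small, and the counts of genes that differ by it too high. The z test also treats the 2 changes as independent. For CyrKO against Mir7DKO, which share their wild-type libraries, this acts the other way and may make its p-values too large. Shared wild-type libraries were treated by 20 simulations of unchanged groups, by splitting the controls, and by a direct test of CyrKO against Mir7DKO.

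The genes named are the network RNAs, the 8 largest rises and 8 largest falls past the threshold at a mean normalised count of at least 50, the 5 smallest p in each direction, list members past the threshold (at most 4 a list), the 6 called miR-7 site genes with the smallest p, and genes called in every Mir7DKO comparison, of which there were none. Other genes named, such as the list members past the adjustment over the list alone, the genes that differed between comparisons and Wdfy1 in experiment 1B, were chosen after their values were seen. The result of 1 gene is not reported here. The groups, tests, lists and naming rule, and the alternatives except those said to be chosen later, were fixed before the data were examined.

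The steps were tested on simulated data with 50 genes changed at each fold size among the genes of each comparison. Of genes changed 2-fold, 84% were recovered in CyrMut, 90% in CyrKO, 84% in Mir7DKO of experiment 1B, 92% in cerebellum and 94% in cortex of experiment 2, and of genes changed 1.5-fold 58%, 66%, 70%, 72% and 80%, with 7, 16, 15, 1 and 13 false calls. A shift of 0.05 put on all site genes was recovered in the 5 comparisons by camera. A shift of 0.02 passed in both tissues of experiment 2 and not in CyrMut, CyrKO or Mir7DKO of experiment 1B. Genes were simulated independently of each other. In the real wild-type libraries of the CyrMut comparison, the mean log2 level of site genes minus that of genes with no site had an SD of 0.029. Shifts of this size may therefore be harder to recover in the real data. Alternatives tried were DESeq2 and its scaling, no filter on low counts, other thresholds, a replicate block, leaving out each library, other site rules and floors, other settings of camera, and a choroid plexus index as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.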

Results

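Polyadenylated RNA was sequenced from the brains of male C57Bl/6J mice aged 1 month, in 33 stranded libraries that fall into 9 groups. The mutants were mice with a mutated miR-7 site in the long noncoding RNA Cyrano (CyrMut), mice lacking Cyrano (CyrKO), and mice labelled as lacking the microRNA genes Mir7a1 and Mir7b (Mir7DKO). Cyrano carries a site of extensive pairing to miR-7, a microRNA that represses messenger RNAs through short 3′ UTR matches, and Cdr1as is a circular RNA with many miR-7 sites. Experiment 1A compared cerebella of 3 wild-type and 4 CyrMut mice, and experiment 1B compared cerebella of 4 wild-type, 4 CyrKO and 4 Mir7DKO mice. Experiment 2 compared 4 wild-type with 3 Mir7DKO libraries in cerebellum and again in cortex. The libraries of experiment 1A held 12.58 to 24.94 M counts. Those of the CyrKO comparison held 8.15 to 13.78 M and those of the Mir7DKO comparison of experiment 1B 9.48 to 14.92 M. In experiment 2 they held 9.77 to 12.86 M in cerebellum and 6.89 to 10.46 M in cortex. Levels are given as CPM (counts per M counts of the library) with the SD between libraries, and changes as log2 of mutant over wild type with their standard error (SE).

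The CyrMut comparison asks which transcripts depend on the miR-7 site of Cyrano. Cyrano (1700020I14Rik, ENSMUSG00000085438, a lincRNA on the + strand of chromosome 2 from 119594297 to 119607502, GRCm38) was at 1697 ± 161 CPM in wild type (n = 3) and 1962 ± 36.7 CPM in CyrMut (n = 4), a log2 change of 0.21 (SE 0.061, adjusted p = 0.944). Its level does not check the genotype, because a change of bases need not change the amount of a transcript. Cdr1as fell by 3.33 on the log2 scale (SE 0.090, adjusted p = 9.7e-09), from 1109 ± 101 CPM (n = 3) to 110 ± 11.5 CPM (n = 4). The wild-type libraries lay between 1044 and 1226 CPM and the CyrMut libraries between 94.7 and 122 CPM. C230004F18Rik, a lincRNA whose gene spans the Cdr1 locus on chromosome X, was at 16.3 ± 4.77 CPM in wild type (n = 3) and 16.2 ± 2.90 CPM in CyrMut (n = 4), a change of -0.02 (SE 0.18) that did not pass the test.

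Cdr1as was the only 1 of 14866 genes that passed the edgeR test in CyrMut, with 0 genes higher, 740 genes at an unadjusted p under 0.05, and 4 genes called by DESeq2. The next gene by p was Dlk1, which encodes a membrane protein related to Notch ligands, at 0.73 ± 0.42 CPM in wild type (n = 3) and 4.65 ± 1.43 CPM in CyrMut (n = 4), a change of 2.81 (SE 0.36, adjusted p = 0.063). The authors' deposited table lists Dlk1 with a log2 change of 2.78 and an adjusted p of 5.8e-10, and also lists Pcolce2 at 1.21 (adjusted p = 0.021) and Ezr at 0.68 (adjusted p = 0.018). Pde10a, a phosphodiesterase, was at 211 ± 56.2 CPM in wild type (n = 3) and 115 ± 15.1 CPM in CyrMut (n = 4), a change of -0.87 (SE 0.16) that did not pass (adjusted p = 0.704). The axonemal gene Dnali1 was 1.55 higher (SE 0.24, adjusted p = 0.218) and the metalloproteinase inhibitor Timp4 had a change of -0.25 (SE 0.053, adjusted p = 0.707). Without CyrMut replicate 2 the test called 17 genes, and without wild-type replicate 2 or replicate 3 it called 2.

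Of the 32 gene lists, 7 passed the set test in CyrMut. The list of Cyrano and the other network RNAs fell, with Cdr1as as the gene that fell over all genes tested, and with Cyrano higher and Cdr1as lower when adjusted over the list alone (set adjusted p = 2.0e-53, adjusted p = 0.0014 with an estimated correlation). Of 14 choroid plexus markers measured, 0 passed over all genes tested and 13 were higher when adjusted over the list alone, with a median log2 change of 2.09. Klotho (Kl), a co-receptor for FGF23, was at 8.15 ± 11.5 CPM in wild type (n = 3) and 41.7 ± 27.1 CPM in CyrMut (n = 4), and the thyroid hormone carrier Ttr was at 100 ± 161 CPM and 598 ± 411 CPM. The libraries did not share this difference, since Ttr was at 13.2 CPM in CyrMut replicate 2 against 647 to 967 CPM in the other 3, and at 286 CPM in wild-type replicate 1 against 6.38 and 7.49 CPM. The choroid plexus set test gave an adjusted p of 1.1e-15, and adjusted p = 0.375 with an estimated correlation. Of 7 erythrocyte genes, 0 passed over all genes and 5 were lower when adjusted over the list alone (Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Alas2, hemoglobin chains and an enzyme of heme synthesis), with a median of -1.15 (set adjusted p = 5.6e-07, adjusted p = 0.375 with an estimated correlation). Of 6 ependymal markers 0 passed over all genes and 2, the ciliary genes Foxj1 and Tekt1, were higher when adjusted over the list alone (set adjusted p = 9.1e-04, adjusted p = 0.346 with an estimated correlation). The brainstem markers (Nefh and Glra1 higher when adjusted over the list alone, median 0.20) and the midbrain markers (Meis2 and Otx2, median 0.08) passed the set test at adjusted p = 0.0021 and 0.021, and had adjusted p = 0.375 and 0.346 with an estimated correlation. Otx2 is also on the choroid plexus list. The 16 oligodendrocyte markers had a median of 0.07 with 0 members past the test on either adjustment (set adjusted p = 0.024, adjusted p = 0.603 with an estimated correlation).

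The CyrKO comparison asks what follows the loss of the whole Cyrano transcript. Cyrano fell by 4.53 on the log2 scale (SE 0.089, adjusted p = 1.1e-12), from 1846 ± 182 CPM in wild type (n = 4) to 80.0 ± 5.97 CPM in CyrKO (n = 4). Every CyrKO library held between 74.7 and 88.3 CPM of Cyrano and every wild-type library of the experiment at least 1579 CPM, so no library went against its label. Cdr1as fell by 3.02 (SE 0.17, adjusted p = 3.7e-07), from 952 ± 214 CPM (n = 4) to 118 ± 22.3 CPM (n = 4). Nusap1 (ENSMUSG00000027306), a microtubule-binding protein of the mitotic spindle, rose by 3.92 (SE 0.15, adjusted p = 4.9e-09), from 1.26 ± 0.29 CPM (n = 4) to 19.3 ± 1.67 CPM (n = 4). Nusap1 lies on the same strand of chromosome 2 from 119618298 to 119651244, 10796 bp past the end of Cyrano, and its annotated 3′ UTR has 1 miR-7 site.

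**Figure D1:**
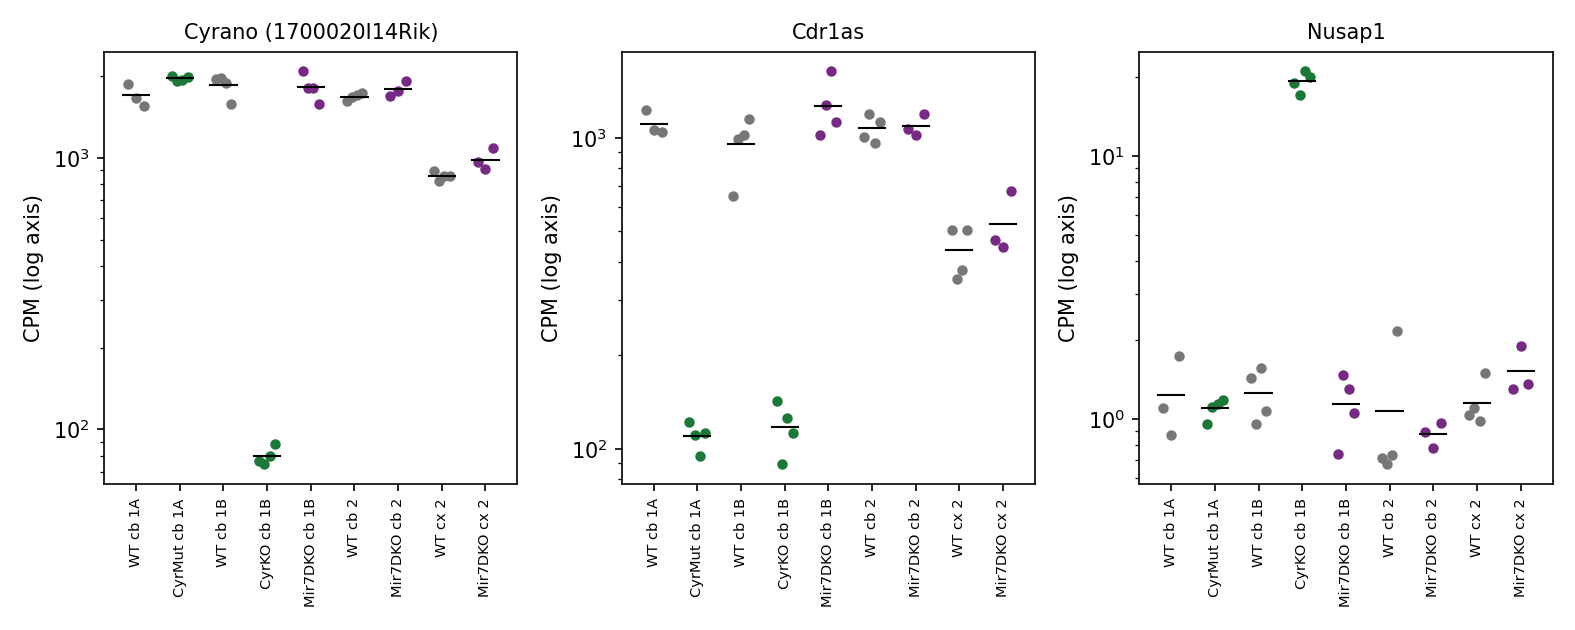
Levels of Cyrano, Cdr1as and Nusap1 in CPM on log axes, 1 point per library and a line at the group mean, for the 9 groups (cb, cerebellum, cx, cortex, with the experiment after it). Cdr1as lies between 94.7 and 122 CPM in CyrMut and between 89.5 and 142 CPM in CyrKO, and Nusap1 lies between 17.1 and 21.0 CPM in CyrKO.

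These 3 of 13664 genes passed the edgeR test in CyrKO, 1 higher and 2 lower, against 1004 genes at an unadjusted p under 0.05, and the same 3 genes passed with DESeq2. The genes next in order did not pass. Cox6a1, a subunit of cytochrome c oxidase, had a change of -0.38 (SE 0.076, adjusted p = 0.598), the stress-induced mTOR inhibitor Ddit4 one of -0.53 (SE 0.11, adjusted p = 0.598), acetylcholinesterase (Ache) one of -0.35 (SE 0.075, adjusted p = 0.598) and the nuclear pore gene Nup37 one of 0.96 (SE 0.20, adjusted p = 0.598). C230004F18Rik was at 15.8 ± 3.82 CPM in wild type (n = 4) and 16.9 ± 2.56 CPM in CyrKO (n = 4), and Hnrnpk, whose gene holds Mir7-1, was at 211 ± 12.7 and 216 ± 12.8 CPM, neither past the test. Without wild-type replicate 4 the test called 10 genes in CyrKO, and leaving out any other library left the count within 1.5 times of 3.

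Of the 32 lists, 3 passed the set test in CyrKO. The network RNAs fell, 2 of 3 measured members passing both over all genes and when adjusted over the list alone (set adjusted p = 4.8e-181, adjusted p = 3.6e-06 with an estimated correlation). Cyrano, the gene removed in CyrKO, is 1 of these members, so the fall of this set was largely fixed by the genotype. C230004F18Rik shares its list entry with Cdr1as and was not counted in the set. Of 19 measured genes around the Cyrano locus, 1, Nusap1, rose over all genes and when adjusted over the list alone, and 18 did not pass. The median of that list was -0.03 while its mean was 0.18 and its test pointed up (set adjusted p = 0.0095, adjusted p = 0.287 with an estimated correlation). Chp1, a calcineurin-like protein gene 7270 bp from Cyrano, had a change of 0.07 (SE 0.058), and the largest other change among the 22 genes measured within 500 kb was 0.65 (SE 0.21) for Exd1, which did not pass. The 7 erythrocyte genes had a median of 0.44 with 0 members past the test on either adjustment (set adjusted p = 0.0095, adjusted p = 0.835 with an estimated correlation).

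**Figure D2:**
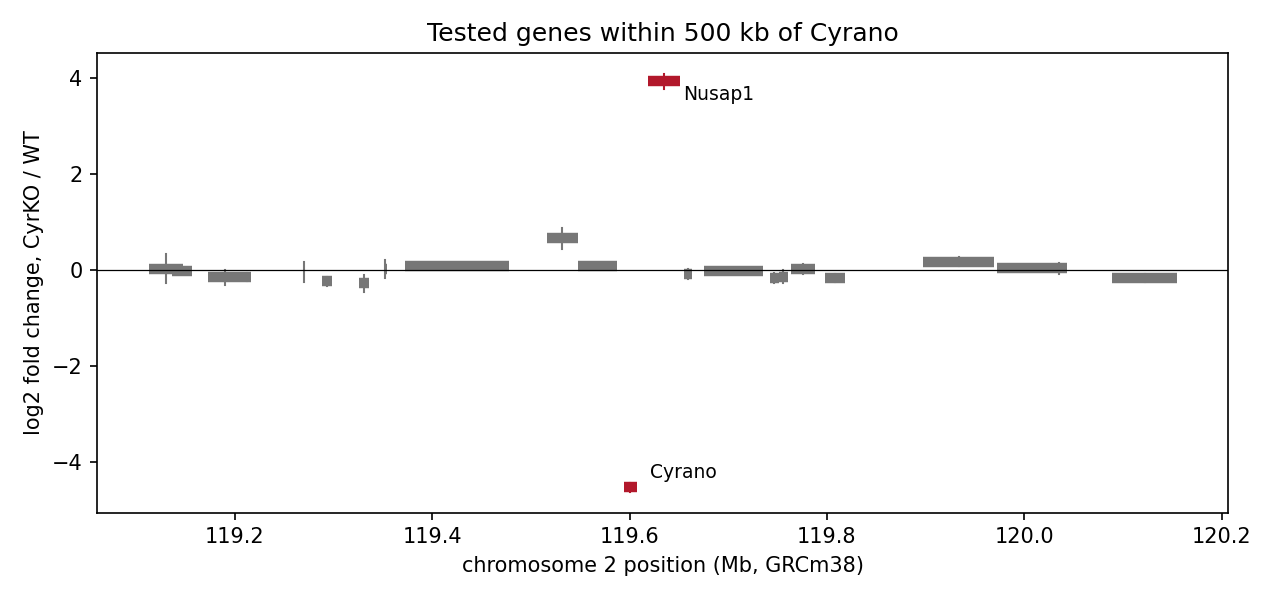
Log2 fold change of CyrKO over wild type for the genes measured within 500 kb of Cyrano, drawn at their positions on chromosome 2 (GRCm38, in Mb). Thick bars span the genes and thin lines are ± 1 SE. Nusap1, at 3.92, and Cyrano, at -4.53, stand apart from the other genes, which lie between -0.28 and 0.65.

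In experiment 1B the Mir7DKO cerebella ask which transcripts depend on miR-7. The libraries select polyadenylated RNA and do not measure mature miR-7, so they do not check this genotype. Mir7b (chromosome 17, 56242988 to 56243098) had 0 counts in the 4 wild-type libraries and 17 counts over the 4 Mir7DKO libraries, 2 to 7 in each. Mir7-1 (chromosome 13, 58392779 to 58392886, inside Hnrnpk) had 9 counts over the wild-type and 11 over the Mir7DKO libraries. Mir7-2 (chromosome 7), a miR-7 gene that the label does not name as deleted, had 0 in both. These few counts do not run in the direction of a deletion. Which bases were deleted is not given in the sources used here, so Mir7DKO stands for the libraries labelled so in each direction given. Pisd-ps1, a transcribed pseudogene of a phosphatidylserine decarboxylase, rose by 1.91 (SE 0.24, adjusted p = 0.047), from 14.6 ± 2.33 CPM in wild type (n = 4) to 55.3 ± 23.0 CPM in Mir7DKO (n = 4). It shares sequence with other copies, so its count is uncertain. Cd59a, an inhibitor of the complement membrane attack complex, was at 6.43 ± 0.32 CPM in wild type (n = 4) and 12.9 ± 2.73 CPM in Mir7DKO (n = 4), a change of 1.01 (SE 0.15) that did not pass (adjusted p = 0.128), although each Mir7DKO library, at 10.0 CPM or more, lay above each wild-type library, at 6.80 CPM or less. Cdr1as was at 954 ± 216 CPM in wild type (n = 4) and 1264 ± 270 CPM in Mir7DKO (n = 4), a change of 0.41 (SE 0.17) that did not pass, and Cyrano was at 1850 ± 178 and 1815 ± 210 CPM.

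Pisd-ps1 was 1 gene higher, with 0 lower, of 14031 genes in the edgeR test of this comparison. There were 516 genes at an unadjusted p under 0.05, and DESeq2 called 3 genes, all higher, of which 1 was shared. The authors' deposited table lists those 3 as Pisd-ps1 at 1.92 (adjusted p = 3.6e-06), Cd59a at 1.01 (adjusted p = 1.4e-04) and Pisd-ps2 at 1.44 (adjusted p = 0.0096). The calcium-binding protein gene Calb2 had a change of -0.28 (SE 0.059) and the basement membrane collagen Col4a1 one of -0.43 (SE 0.10), and neither passed. Without any of wild-type replicates 1, 2, 3 and 4 or Mir7DKO replicates 1 and 3 the test called 0 genes, and without Mir7DKO replicate 2 or 4 it called 2. Wdfy1, which encodes an endosomal FYVE-domain protein, was at 48.6, 50.8, 31.6 and 31.0 CPM in the 4 Mir7DKO libraries and at 32.0 ± 2.57 CPM in wild type (n = 4), a change of 0.34 (SE 0.15) that did not pass.

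Of the 32 lists, 6 passed the set test in Mir7DKO of experiment 1B, and none of them held with an estimated correlation. The 7 measured mitochondrially encoded mRNAs were higher as a set with a median of 0.17, 0 members past the test over all genes and 1, mt-Nd5, when adjusted over the list alone (set adjusted p = 2.4e-07, adjusted p = 0.541 with an estimated correlation). The other 5 lists were lower as sets, with 0 members past the test on either adjustment. They were the 16 oligodendrocyte markers (median -0.16, set adjusted p = 4.8e-07, adjusted p = 0.541 with an estimated correlation), the 50 measured cytosolic ribosomal proteins (median -0.06, adjusted p = 0.0023 and 0.541) and the 22 genes of the unfolded protein and integrated stress response (median -0.13, adjusted p = 0.0035 and 0.624). The other 2 were the 7 erythrocyte genes (median -0.80, adjusted p = 0.021, and adjusted p = 0.765 with an estimated correlation) and the 21 measured genes of cholesterol synthesis (median -0.08, adjusted p = 0.035, and adjusted p = 0.624 with an estimated correlation).

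In experiment 2 the same Mir7DKO comparison was made with other cerebella. Cd59a rose by 1.40 (SE 0.13, adjusted p = 2.8e-06), from 6.25 ± 0.50 CPM in wild type (n = 4) to 16.5 ± 1.98 CPM in Mir7DKO (n = 3). Wdfy1 rose by 0.78 (SE 0.081, adjusted p = 1.8e-05), from 29.4 ± 3.58 CPM (n = 4) to 50.6 ± 0.41 CPM (n = 3). Trim37, an E3 ubiquitin ligase, fell by 0.33 (SE 0.052, adjusted p = 0.0061), from 401 ± 11.2 CPM (n = 4) to 318 ± 22.6 CPM (n = 3), and Padi2, a peptidylarginine deiminase, fell by 0.42 (SE 0.084, adjusted p = 0.032), from 35.7 ± 2.54 CPM (n = 4) to 26.8 ± 2.34 CPM (n = 3). For these 4 genes every Mir7DKO library lay beyond every wild-type library. Cdr1as lay between 961 and 1195 CPM in wild type (n = 4) and between 1017 and 1192 CPM in Mir7DKO (n = 3), a change of 0.03 (SE 0.064) that did not pass. Mir7b had 0 counts in wild type and 12 over the Mir7DKO libraries, and Mir7-1 had 5 and 8, again not in the direction of a deletion.

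Of 14146 genes, 22 rose and 6 fell in the edgeR test of this cerebellar comparison, against 959 at an unadjusted p under 0.05, and DESeq2 called 25, of which 17 were shared. The largest changes included several choroid plexus markers. Ttr rose by 6.01 (SE 0.80, adjusted p = 9.1e-04), from 4.90 ± 2.77 CPM (n = 4) to 315 ± 291 CPM (n = 3). Kl rose by 3.66 (SE 0.55), the prolactin receptor Prlr by 3.16 (SE 0.54) and the bicarbonate transporter Slc4a5 by 2.59 (SE 0.46). The coagulation factor F5 (3.04, SE 0.54) and the carbonic anhydrase Car12 (2.94, SE 0.51), which are not on the marker list, rose as well. Of 9 choroid plexus markers measured, 5 rose over all genes tested, 8 were higher when adjusted over the list alone, and the median change was 1.74 (set adjusted p = 1.1e-24, adjusted p = 0.303 with an estimated correlation). The Mir7DKO libraries did not share this rise, since Ttr was at 580 and 360 CPM in replicates 1 and 2 and at 3.47 CPM in replicate 3. Other genes that rose were the cytoskeletal linker Msn (0.43, SE 0.079), the chemokine Cxcl12 (0.33, SE 0.065) and the intermediate filament Nes (0.62, SE 0.12). Others that fell were Renbp, a renin-binding protein (-1.18, SE 0.22), Gas7, a cytoskeletal adaptor (-0.35, SE 0.065), and the uncharacterised Gm10524 (-0.62, SE 0.13). The called genes with a miR-7 site were Msn, Col8a1, Car12, Slc4a5 and Htr2c among those that rose, and Padi2 and Gas7 among those that fell. None of the 7 passed with the choroid plexus index as a covariate. In that fit Car12 was at 0.21 (SE 0.47), Slc4a5, itself part of the index, at 0.09 (SE 0.40), Htr2c at -0.08 (SE 0.23) and Col8a1 at 0.64 (SE 0.33). Msn at 0.44 (SE 0.10), Gas7 at -0.28 (SE 0.088) and Padi2 at -0.39 (SE 0.12) stayed near their values without the covariate, with larger SE.

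The count of 28 in cerebellum depended on single libraries. It was 3 without wild-type replicate 1 or 2, 6 without wild-type replicate 4, 67 without Mir7DKO replicate 2 and 70 without Mir7DKO replicate 3, and 16 with the choroid plexus index as a covariate, a fit chosen after the data had been seen in which 5 of the 28 genes were kept and Cd59a and Wdfy1 were among them. In that fit F5, which is not part of the index, had a change of -0.01 (SE 0.45). Kl had one of 0.49 (SE 0.34) and Prlr one of 0.28 (SE 0.51), but both are part of the index, so their fall is partly built in. Trim37 had a change of -0.27 (SE 0.067, adjusted p = 0.148) and Padi2 one of -0.39 (SE 0.12, adjusted p = 0.267).

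Of the 32 lists, 8 passed the set test in this comparison and none of them held with an estimated correlation. Besides the choroid plexus, the 12 meningeal fibroblast markers were higher as a set (median 0.20, set adjusted p = 4.2e-04, adjusted p = 0.485 with an estimated correlation), with 0 members past the test on either adjustment. Of 26 measured immediate early genes, 0 passed over all genes and 3 transcription factors, Npas4 at 0.88, Klf4 at 0.81 and Fosl2 at 0.49, were higher when adjusted over the list alone (set adjusted p = 0.0499, adjusted p = 0.670 with an estimated correlation). The 21 measured interferon response genes were lower as a set with a median of -0.29 and 0 members past the test on either adjustment (set adjusted p = 0.0070, adjusted p = 0.670 with an estimated correlation). The Purkinje cell (median -0.07, set adjusted p = 0.027), oligodendrocyte (median -0.06, set adjusted p = 0.0093) and brainstem markers (median -0.19, set adjusted p = 0.0499) were also lower as sets with 0 members past the test on either adjustment, each with adjusted p = 0.560 with an estimated correlation. Of 9 cortical interneuron markers measured in cerebellum 0 passed over all genes and 1, Calb2 at -0.27 (SE 0.063), was lower when adjusted over the list alone (set adjusted p = 0.029, adjusted p = 0.485 with an estimated correlation). Calb2 is also a marker on the granule neuron list.

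In cortex of experiment 2 the same 4 genes passed the test again. Wdfy1 rose by 0.86 (SE 0.072, adjusted p = 5.2e-06), from 23.1 ± 0.90 CPM in wild type (n = 4) to 42.0 ± 1.03 CPM in Mir7DKO (n = 3), and Cd59a rose by 1.51 (SE 0.19, adjusted p = 6.6e-04), from 2.98 ± 0.70 CPM to 8.52 ± 0.75 CPM. Padi2 fell by 0.70 (SE 0.075, adjusted p = 1.3e-04), from 43.6 ± 2.65 CPM to 26.8 ± 1.17 CPM, and Trim37 fell by 0.38 (SE 0.050, adjusted p = 0.0014), from 554 ± 27.3 CPM to 426 ± 17.7 CPM. Cd93, a receptor of endothelial cells, rose by 0.50 (SE 0.083, adjusted p = 0.027), from 19.1 ± 0.81 CPM to 27.2 ± 1.46 CPM. Ttr fell by 5.78 (SE 1.01, adjusted p = 0.041), from 164 ± 161 CPM to 2.96 ± 0.98 CPM, with the 4 wild-type libraries spread from 3.31 to 317 CPM. Mir7b had 0 counts in wild type and 2 in Mir7DKO, and Mir7-1 had 1 and 1. Cdr1as was at 435 ± 82.0 CPM in wild type (n = 4) and 529 ± 125 CPM in Mir7DKO (n = 3), a change of 0.29 (SE 0.12) that did not pass.

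**Figure D3:**
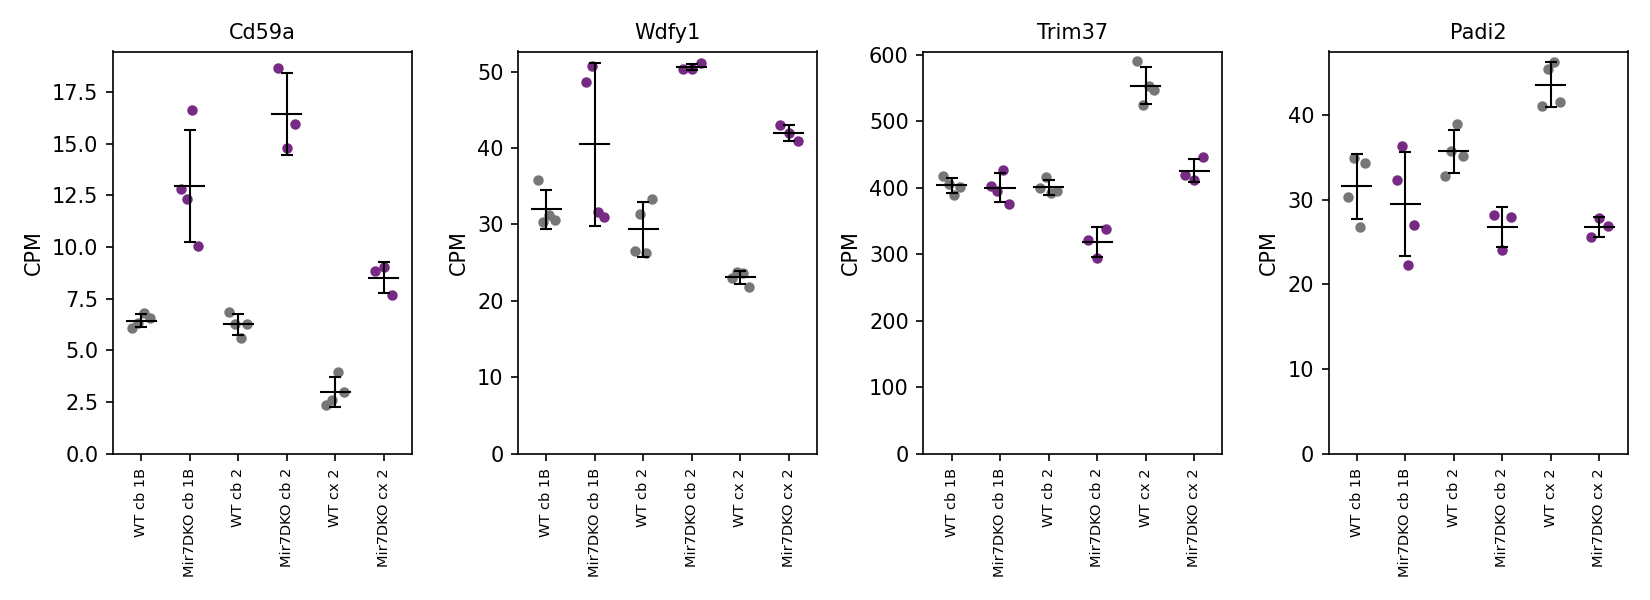
Levels of Cd59a, Wdfy1, Trim37 and Padi2 in CPM, 1 point per library, with the group mean and an error bar of ± 1 SD, in the wild-type and Mir7DKO groups (cb, cerebellum, cx, cortex, with the experiment after it). In experiment 2 the mutant libraries lie beyond the wild-type libraries for each gene. In experiment 1B this holds for Cd59a, while Trim37 is at 403 CPM in wild type and 400.2 CPM in Mir7DKO on average.

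These 6 of 13754 genes, 3 higher and 3 lower, passed the edgeR test in cortex, against 793 at an unadjusted p under 0.05, and DESeq2 called 6 with 5 shared. Epas1, a hypoxia-inducible transcription factor, had a change of -0.29 (SE 0.057) and did not pass (adjusted p = 0.126), while the authors' deposited table lists it at -0.30 with an adjusted p of 0.015. The water channel Aqp4 of astrocytes had a change of 0.21 (SE 0.046, adjusted p = 0.360) and Mid1, a microtubule-associated ubiquitin ligase, one of 1.34 (SE 0.30, adjusted p = 0.340). Without wild-type replicate 1 the test called 11 genes in cortex. The call of Ttr was lost without wild-type replicate 3 or 4 or any 1 of the 3 Mir7DKO libraries (adjusted p = 0.19, 0.13, 0.43, 0.33 and 0.55), and that of Cd93 in 6 of the 7 such fits. With the choroid plexus index as a covariate, Trim37 had a cortical change of -0.37 (SE 0.068, adjusted p = 0.060) and Cd93 one of 0.51 (SE 0.11, adjusted p = 0.335), so both calls were lost, while those of Wdfy1, Padi2, Cd59a and Ttr were kept.

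**Figure D4:**
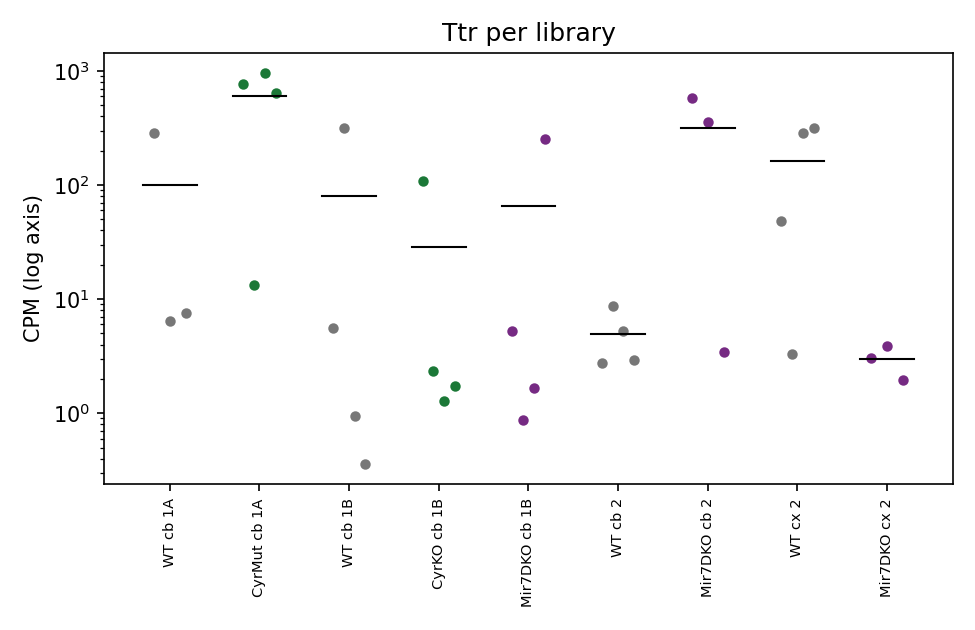
Level of Ttr in CPM on a log axis, 1 point per library and a line at the group mean, for the 9 groups (cb, cerebellum, cx, cortex, with the experiment after it). Libraries of 1 group differ widely, from 3.31 to 317 CPM in wild-type cortex and from 3.47 to 580 CPM in Mir7DKO cerebellum of experiment 2.

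Of the 32 lists, 8 passed the set test in cortex and none of them held with an estimated correlation. Of 6 choroid plexus markers measured, 1, Ttr, fell over all genes, 5 were lower when adjusted over the list alone, and the median was -1.23 (set adjusted p = 3.2e-10, adjusted p = 0.480 with an estimated correlation). Of 16 endothelial and mural markers 0 passed over all genes and 2, the tight junction gene Cldn5 at 0.35 and the VEGF receptor Flt1 at 0.16, were higher when adjusted over the list alone (set median 0.13, set adjusted p = 4.8e-05, adjusted p = 0.480 with an estimated correlation). The network RNAs were higher as a set with a median of 0.20, 0 of 3 members past the test over all genes and Cyrano, at 858 ± 30.4 CPM in wild type (n = 4) and 984 ± 91.2 CPM in Mir7DKO (n = 3), when adjusted over the list alone (set adjusted p = 0.012, adjusted p = 0.480 with an estimated correlation). The immediate early genes were higher as a set with 0 of 29 members past the test over all genes and Egr1, at 0.35 (SE 0.085), when adjusted over the list alone (set adjusted p = 0.038, adjusted p = 0.612 with an estimated correlation). In the other 4 lists 0 members passed on either adjustment. The 15 measured oligodendrocyte markers were lower as a set (median -0.08, set adjusted p = 9.0e-04), and the 15 microglia markers (median 0.07, set adjusted p = 0.034) and 18 interferon response genes (median 0.08, set adjusted p = 0.020) were higher, each with adjusted p = 0.575 with an estimated correlation. The 12 striatum markers were higher (median 0.14, set adjusted p = 0.044, adjusted p = 0.705 with an estimated correlation).

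Genes with a miR-7 site in the 3′ UTR were then compared with genes lacking one. In CyrMut the 3289 site genes had a median log2 change 0.0055 above that of 4841 genes with no site (exact permutation p = 0.514 over the libraries). In Mir7DKO the difference was -0.00016 in experiment 1B (exact permutation p = 1), 0.0084 in cerebellum of experiment 2 (exact permutation p = 0.6) and 0.0052 in cortex (exact permutation p = 0.629). None of these 4 differences passed camera. In CyrKO the 3116 site genes lay 0.024 above 4429 genes with no site (camera p = 0.0447, and p = 0.0031 with an estimated correlation), with an exact two-sided permutation p of 0.0286 over the libraries, the smallest this design allows. Against genes not counted as having a site and matched on expression and 3′ UTR length, the CyrKO difference was -0.0068. Its sign thus turned, and it did not pass camera. The matched genes may hold shorter seed matches. The match in length was incomplete, with a median 3′ UTR of 2448.5 bases for site genes and 2052 for matched genes. Of 60 shuffled miR-7 seeds, 13 gave a plain difference as high in CyrKO and 12 passed camera themselves. In Mir7DKO of experiment 1B, 1 of 60 was as high, and 4 of 60 against matched genes. In cerebellum of experiment 2 these numbers were 27 and 27, in cortex 10 and 10, and in CyrMut 46 and 47. The median of the CyrKO site genes, 0.0070, lay below all 10000 random lists matched on expression and 3′ UTR length, of which 95% had medians from 0.013 to 0.022. That of the CyrMut site genes, -0.0043, also lay below all of its random lists. The random lists draw genes as if they varied independently. Against matched genes, 43 of 60 shuffled seeds gave a difference as low as that of miR-7 in CyrKO and 17 one as high. In CyrMut 13 of 60 were as low, so the low position was not particular to the miR-7 seed. The 35 measured miR-7 targets reported in the literature had medians of -0.04 in CyrMut, -0.02 in CyrKO, -0.01, 0.01 and 0.01 in the 3 Mir7DKO comparisons, with set adjusted p from 0.172 to 0.831. Of them 0 passed over all genes in any comparison and 1, Klf4 in Mir7DKO cerebellum of experiment 2, when adjusted over the list alone. In Mir7DKO of experiment 1B their median was below 0 and their mean above it.

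**Figure D5:**
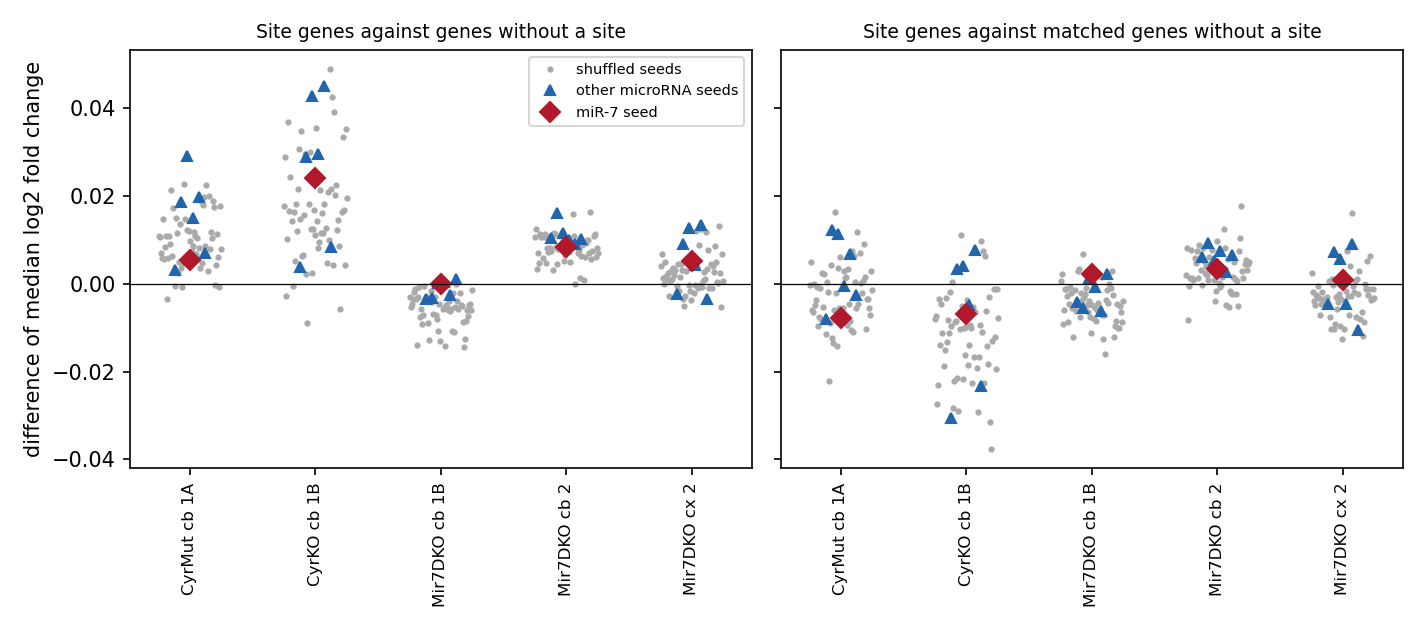
Difference of the median log2 fold change of genes with a 3′ UTR site from genes without one, for the 5 comparisons, with all genes without a site (left) and with genes matched on expression and 3′ UTR length (right). The miR-7 seed lies inside the range of the 60 shuffled seeds in every comparison and both panels.

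The Mir7DKO changes of the 2 experiments in cerebellum correlated weakly across 11332 genes, which are not independent replicates (Spearman rho 0.060, jackknife SE 0.11 over libraries), and 52.4% of genes had the same sign. Of 27 genes called in experiment 2 and measured in both, 16 had the same sign in experiment 1B. The change differed between the experiments for 10 of 13893 genes by the z test, with 725 at an unadjusted p under 0.05. These p-values may be too small with so few libraries per group. Trim37 was among them (-0.01, SE 0.053, in experiment 1B and -0.33, SE 0.052, in experiment 2, z = 4.33, adjusted p = 0.023), as were Pisd-ps1, Msn, Renbp and Nes, while Cd59a (z = -1.98, adjusted p = 0.946) and Wdfy1 (z = -2.57, adjusted p = 0.722) did not pass. The count was 32 without wild-type replicate 4 of experiment 1B, 28 and 19 without its Mir7DKO replicates 2 and 4, and 18 and 32 without Mir7DKO replicates 2 and 3 of experiment 2.

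Between cerebellum and cortex of experiment 2 the Mir7DKO changes differed for 35 of 13191 genes, with 764 at an unadjusted p under 0.05, and rho across 10446 genes was 0.12 (jackknife SE 0.14) while Pearson's r was -0.18. Cd59a and Wdfy1 passed upward in both tissues and Trim37 and Padi2 downward in both, where independent lists would share 0.0045 genes upward and 0.0014 downward, and Ttr passed in opposite directions. The labels do not say whether both tissues came from the same animals. The difference test and the expected overlap of independent lists both treat them as separate. The count was 17 without Mir7DKO cerebellum replicate 1, 53 without its replicate 3 and 19 without wild-type cortex replicate 4.

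CyrKO and Mir7DKO of experiment 1B were compared with the same 4 wild-type libraries. Across 11229 genes rho was 0.31 (jackknife SE 0.26, 0.187 without Mir7DKO replicate 1 and 0.441 without wild-type replicate 2), Pearson's r 0.286 and the covariance 0.0042, and 60.5% of genes had the same sign. Simulated unchanged groups against shared controls gave 0.472, 0.496, 0.0073 and 66.5% as means of 20 simulations. With the controls split between the comparisons, the mean over 6 splits was -0.090 for rho, from -0.354 to 0.039, and -0.0043 for the covariance. Tested directly, CyrKO differed from Mir7DKO in 7 of 13814 genes, with 1410 at an unadjusted p under 0.05. These were Cyrano (-4.49, SE 0.097), Cdr1as (-3.41, SE 0.16), Cd59a (-1.09, SE 0.16), the mitochondrial gene Chchd10 (-0.46, SE 0.064) and Fndc4 (-0.37, SE 0.057) as lower in CyrKO, and Nusap1 (4.03, SE 0.16) and the noncanonical poly(A) polymerase Fam46c (1.19, SE 0.18) as higher. From the difference of the fold changes 6 genes passed, with 414 at an unadjusted p under 0.05, and 11 passed without Mir7DKO replicate 1. That z test makes no allowance for the shared wild-type libraries, so its p-values may be too large here. The direct test called 99 genes without Mir7DKO replicate 1, 3 without CyrKO replicate 1, 2 or 3 or Mir7DKO replicate 2, and 4 without Mir7DKO replicate 3 or 4.

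The CyrMut and CyrKO changes came from separate wild-type libraries. Cdr1as was lower in both by amounts that did not differ past the test (z = -1.65), and it was the 1 gene shared by their calls, where independent lists would share 0.00015. Across 11231 genes rho was 0.28 (jackknife SE 0.32) and 60.9% of genes had the same sign. The change differed for 4 of 13652 genes, with 695 at an unadjusted p under 0.05: Cyrano, Nusap1 (z = -12.95), Pcolce2 and Mir3097. That count was 33 without CyrMut replicate 2, 7 without wild-type replicate 2 of experiment 1A, 14 without wild-type replicate 4 of experiment 1B and 2 without CyrKO replicate 4.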

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

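The split counts, the test of choroid plexus carry-over and the prediction on dividing cells were set before their results were seen, and the other tests named here were chosen only after the result was seen. Across 158 groups of 4 libraries, 11 had a library far from the other 3 by Dixon's ratio, and chance flags about 1 in 20 groups. The choroid plexus index (mean log2 level of the markers, centred) was far from the rest in CyrMut replicate 2 (-1.87), wild-type replicate 2 of experiment 1B (2.08), CyrKO replicate 1 (1.19) and Mir7DKO replicate 4 of experiment 1B (1.65). The oligodendrocyte index was at 0.11 in wild-type replicate 2 of experiment 1B and at -0.45 in CyrKO replicate 2, whose brainstem index was at -0.70. The cortical interneuron index was at 0.11 in wild-type replicate 3 of experiment 1B, and the astrocyte and Bergmann glia index at -0.13 in CyrKO replicate 4. Pisd-ps1 was at 89.7 CPM in Mir7DKO replicate 4 of experiment 1B against 41.9 to 46.9 CPM in the other 3. The miR-7 site index was at -0.0184 in wild-type cerebellum replicate 1 of experiment 2.

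The Mir7DKO change differed between cerebellum and cortex for 35 genes by the z test, and those reported here are given as the cerebellar minus the cortical log2 change. The largest differences were those of Ttr (11.79), F5 (5.65), Kl (5.53), Prlr (4.42), 1500015O10Rik (3.30), Car12 (3.16), Abca4 (2.65), Trpv4 (2.50), Kcnj13 (2.44), Zfp185 (2.31), Efcab1 (2.20) and Enpp2 (2.04). They were followed by Clic6 (1.958), Col8a2 (1.88), Lbp (1.80), Myo5b (1.71), Npr3 (1.61), Col8a1 (1.61), Htr2c (1.46), Adamtsl2 (1.44), Dnah9 (1.42), Fam83h (1.31), Moxd1 (1.30) and Npas4 (1.20). Smaller ones were those of Igfbp2 (0.75), Col9a3 (0.66), Sod3 (0.64), Cab39l (0.59), D930016D06Rik (0.47) and Msn (0.43). Taf1a (-1.05), Rybp (-0.60), Cntn6 (-0.43) and Gas7 (-0.31) were the genes with a lower change in cerebellum. Outside the comparisons, Mir7b had 17 counts over the Mir7DKO libraries of experiment 1B, 12 over those of experiment 2 in cerebellum and 2 in cortex, with 0 in wild type each time. Mir7-1 had 11 against 9, 8 against 5 and 1 against 1, so in no comparison did these counts run in the direction of a deletion.

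Choroid plexus genes rose in Mir7DKO cerebellum and Ttr fell in Mir7DKO cortex of experiment 2, which may come from choroid plexus tissue carried over at dissection. A single effect of miR-7 loss in both tissues is argued against by the opposite signs of Ttr, with z = 9.12 for the difference. Within groups the other markers moved with Ttr from library to library, with a median correlation of 0.924, and Otx2 the lowest at 0.385. With the marker index as a covariate the cerebellar change of Ttr went from 6.01 (SE 0.80) to 0.16 (SE 0.33), while the cortical change went from -5.78 (SE 1.01) to -2.21 (SE 0.39, adjusted p = 0.048 in edgeR) and still passed, in fits whose index holds Ttr itself. In experiment 1B, Ttr, Kl, Prlr, Enpp2 and Slc4a5 had Mir7DKO changes of -0.26, 0.01, -0.36, -0.27 and -0.13. Ttr there was at 5.30, 0.87, 1.66 and 255 CPM in Mir7DKO and at 5.54, 314, 0.94 and 0.36 CPM in wild type. These values argue against a rise shared by the Mir7DKO cerebella of both experiments. The difference of Ttr between the experiments did not pass the z test (z = -3.51, adjusted p = 0.231). An effect of the genotype confined to cortex or to experiment 2 stays open, as untested.

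Other splits of the same libraries show how far chance can be excluded. For genes changed, 7 of 35 splits gave as many as the real 1 in CyrMut (highest other 90), 2 of 35 as many as 3 in CyrKO (highest other 47), 5 of 35 as many as 1 in Mir7DKO of experiment 1B (highest other 68) and 4 of 35 as many as 6 in cortex (highest other 53), so chance is not excluded for the number of genes. The number does not weigh the size of single changes, such as Cdr1as in CyrMut (-3.33, SE 0.090) or Cyrano (-4.53, SE 0.089) and Nusap1 (3.92, SE 0.15) in CyrKO, where no library of 1 group overlapped the other. Splits with several times the real count point to a possible structure of the samples other than genotype, which was not tested. In cerebellum of experiment 2, 1 of 35 splits, the real one, gave 28 genes (highest other 21). This is the smallest share the design allows, and several such split counts were made, so it does not by itself exclude chance for the number. The 4 highest other splits (21, 9, 8 and 7 genes) all kept Mir7DKO replicates 1 and 2 together, the libraries with Ttr at 580 and 360 CPM, so the number also follows the choroid plexus markers. For the miR-7 site genes, 25, 3, 35, 12 and 24 of 35 splits were as large in CyrMut, CyrKO, Mir7DKO of experiment 1B, and cerebellum and cortex of experiment 2 (real sizes 0.0055, 0.024, 0.00016, 0.0084 and 0.0052, highest others 0.030, 0.026, 0.023, 0.013 and 0.015), and chance is not excluded. These splits weigh the difference of medians. The exact permutation p of 0.0286 in CyrKO weighed another measure, the mean log2 level of site genes minus that of genes with no site per library. For the lists, 13, 32, 18, 2 and 10 of 35 splits passed as many (real 7, 3, 6, 8 and 8, highest others 10, 10, 10, 8 and 15), and chance is not excluded. For genes that differed between comparisons, 22 of 100 splits reached the real 10 of the 2 experiments (highest other 421). The real 4 of CyrMut against CyrKO were reached by 38 of 100 (highest other 1225), and the real 7 of the direct test by 2 of 35 (highest other 114). None of these shares excludes chance for the number, although Cyrano (z = 43.9) and Nusap1 (z = -12.95) differed strongly between CyrMut and CyrKO. The cause of these high counts was not tested. For CyrKO against Mir7DKO, 30 of 100 splits reached the real 6 (highest other 1698). There the 2 comparisons were split separately, so a shared wild-type library could stand as mutant in 1 and as control in the other. Those splits do not keep the shared controls of the real design, so their share cannot decide on chance. Between cerebellum and cortex 3 of 100 splits, the real one among them, reached the real 35 (highest other 45). This share argues against chance only if the tissues came from separate animals, which the labels do not say, and several such split counts were made.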

How the results depend on the processing

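The count of lists with an estimated correlation and the choroid plexus covariate were chosen only after the result was seen. Of 387 settings tried on 24 comparison results, 302 kept the side of the threshold, stayed within 1.5 times or, for rho, within the jackknife SE. Another 37 moved upward or past the threshold, 47 moved downward or below it, and 1 turned its sign where the main or the altered fit passed. The same counts for 851 settings on 75 named genes were 733, 31, 87 and 0. A turned sign where neither fit passed counts as kept, such as the CyrMut site genes against matched genes (0.0055 to -0.0078). Cdr1as in CyrMut and CyrKO, Cyrano and Nusap1 in CyrKO, and Cd59a and Wdfy1 in both tissues of experiment 2 passed under every setting run. Where no cause is named here, the cause was not tested. Pseudocounts were not run, since the values are counts.

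With DESeq2 the count of changed genes was 4 in CyrMut and 3 in Mir7DKO of experiment 1B. With no filter on low counts it was 43 in CyrMut, 10 in CyrKO, 4 in Mir7DKO of experiment 1B, 184 in cerebellum and 48 in cortex of experiment 2, and 11 lists passed in CyrMut. At an adjusted p under 0.1 it was 2 in CyrMut, and 7 genes differed between CyrMut and CyrKO. At 0.01 it was 0 in Mir7DKO of experiment 1B and 5 in cerebellum of experiment 2. With the choroid plexus covariate it was 16 in cerebellum of experiment 2.

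The replicate numbers of the labels were not taken as pairs. Correlations of same-numbered libraries ran from -0.309 to 0.431 and in no comparison were all over 0.1 (0.157, 0.143 and 0.082 in cortex). In cortex, however, each exceeded the best correlation with a library of another number (0.043, -0.009 and -0.015), so pairing is not excluded there. In no other comparison did every same-numbered pair do so. With the replicate block, 2 genes were called in Mir7DKO of experiment 1B and 19 in cortex, 11 lists passed in CyrMut and 4 in cerebellum of experiment 2, and no other comparison result moved by over 1.5 times or changed its call.

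In CyrKO the difference of site genes was 0.014 with 8-mer sites only, 0.025 with a floor of 10 and 0.021 with a floor of 200, none of which passed. The median over shuffled seeds was 0.016. The difference turned to -0.0068 against matched genes, which differ from the plain comparison genes in 3′ UTR length (median 2052 against 645 bases). The site genes had a median of 2448.5 bases, so the match in length was incomplete. The number of lists that passed was, with the rank version of camera, 1 in CyrKO, and with a preset correlation of 0.05, 2 in Mir7DKO of experiment 1B, 2 in cerebellum and 4 in cortex of experiment 2. With an estimated correlation it was 1 in CyrMut, 1 in CyrKO, and 0 in the 3 Mir7DKO comparisons. Without the targeted genes, their chromosomes, Cdr1as and Cdr1, 0 genes differed between CyrKO and Mir7DKO and 0 between CyrMut and CyrKO. Cdr1as, which was left out there by name, did differ between CyrKO and Mir7DKO (z = -14.38, adjusted p = 4.8e-43 in the z test).

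Leaving out each library in turn gave 1 to 17 changed genes in CyrMut, 3 to 10 in CyrKO, 0 to 2 in Mir7DKO of experiment 1B, 3 to 70 in cerebellum and 4 to 11 in cortex of experiment 2. The number of lists was 7 to 13, 1 to 5, 4 to 9, 3 to 10 and 4 to 11 in the same order. The CyrKO site-gene difference was 0.016 to 0.031. The genes that differed were 7 to 32 between the experiments, 17 to 53 between the tissues, 4 to 11 between CyrKO and Mir7DKO, 3 to 99 in their direct test and 2 to 33 between CyrMut and CyrKO. Depth limits genes with few counts, and in the self-test changes of 1.5-fold were missed more often than changes of 2-fold in each comparison.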

Other observations

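The tests on Nusap1 and on the 4 genes of Mir7DKO were chosen only after the result was seen, except the test of dividing cells. Cd59a, Wdfy1, Trim37 and Padi2 did not pass the test in either Cyrano mutant. Wdfy1 was at 28.1 ± 1.81 CPM in wild type (n = 3) and 28.1 ± 2.12 CPM in CyrMut (n = 4), and Trim37 at 399 ± 16.0 and 389 ± 6.83 CPM, while in CyrKO (n = 4) they were at 31.5 ± 1.17 and 416 ± 11.1 CPM against 31.9 ± 2.60 and 403 ± 12.3 CPM in wild type (n = 4), none past the test. Padi2 in CyrKO had a change of -0.30 (SE 0.13, adjusted p = 0.677). Pisd-ps1 varied within groups elsewhere, at 63.1 ± 32.7 CPM in wild-type cerebellum (n = 4) and 75.0 ± 25.3 CPM in wild-type cortex (n = 4) of experiment 2 against 14.6 ± 2.33 CPM in wild type of experiment 1B (n = 4).

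Cd59a, Wdfy1, Trim37 and Padi2 moved in both tissues of Mir7DKO in experiment 2. Direct release of Cd59a and Wdfy1 from miR-7 is argued against by their annotated 3′ UTRs, 0 of which hold a 7-mer or 8-mer site. DNA linked to the edited loci is argued against by the positions of the 4 genes. Of these genes, 0 lie on the chromosomes of the deleted genes named in the label (13 and 17) or on that of Mir7-2 (7), which the label does not name. An effect of miR-7 loss on Trim37 shared by the cerebella of both experiments is argued against by their difference (z = 4.33), whose p-value may be too small with so few libraries. Other DNA differences between the mutant and wild-type animals could act alike in both tissues, and the largest z of the 4 genes between tissues was 2.48. No value reported here gives the animals' genotype elsewhere in the genome. Such differences can thus not be told apart here from an effect of the genotype. The levels of Wdfy1 in Mir7DKO of experiment 1B, 48.6 and 50.8 CPM in 2 libraries and 31.6 and 31.0 CPM in the other 2, stay unexplained.

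Nusap1 rose in CyrKO and did not pass the test in CyrMut, with a change of -0.09 (SE 0.27). Loss of the pairing between Cyrano and miR-7 is argued against by the difference of the mutants (z = -12.95). More dividing cells are argued against by 16 measured mitotic genes, fixed before the test, whose median change was -0.0419 (highest 0.26, Kif11) beside 3.92 for Nusap1. Transcription altered next to the deleted segment may raise it, but 0 other genes of the 22 measured within 500 kb passed the test and gene counts do not show where reads begin, so this stays open.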
